A study of Mus musculus with 3 samples.

How the data were processed

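Single-cell RNA sequencing was available for TEa cells sorted 7 days after heart transplantation. TEa cells are CD4 T cells from mice that carry a transgenic T cell receptor recognising an allopeptide of BALB/c origin. They had been transferred into C57BL/6 mice, which then received BALB/c hearts. The 3 libraries were wild-type TEa cells from the heart allograft, wild-type TEa cells from the spleen, and Ldha-deficient TEa cells from the spleen, with 1 library per group. Libraries were made with droplet-based 3' chemistry, per the labels' protocols. That chemistry reads the 3' ends of transcripts and counts unique molecular identifiers (UMIs).

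The deposited matrices hold raw UMI counts per gene and barcode, with no normalization. Per the file headers, both wild-type matrices were written by Cell Ranger 3.0.2 and the Ldha-deficient matrix by Cell Ranger 7.0.1, while the submitters' processing notes name Cell Ranger 7.0.0, Seurat 4.0.0 and the mm10 build. The treatment of intronic reads was not given in the sources used here. The wild-type matrices list all 6794880 possible barcodes and 28692 named genes, so cells had to be called from them. The Ldha-deficient matrix lists 12516 barcodes, each with at least 505 UMIs, over 32285 rows. Gene names for those rows were not used here. The row number differs from that of the wild-type matrices, and rows were not named from their position. The planned check of Ldha in that library and the planned comparison of Ldha-deficient with wild-type spleen cells by gene were therefore not analysed here.

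Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. The mitochondrial limit, doublet calling and the removal of other cell types were not applied to the Ldha-deficient library. Scrublet, run through scanpy 1.11.5 with an expected doublet rate of 0.06, marked 2 heart barcodes and 0 of 6583 spleen barcodes, and is regarded as not having worked in either library, so doublets can remain among the kept cells. The 2 marked barcodes were removed. The wild-type barcodes were clustered jointly without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a shared-neighbour graph of 15 neighbours was partitioned with the Leiden algorithm (leidenalg 0.10.2) at resolution 0.6. Receptor segments, mitochondrial, ribosomal protein and sex-linked genes were left out of the clustering. Clusters were named only from markers set in advance, and 1 cluster with monocyte or macrophage markers was removed. Of 11 clusters, 9 drew over 90% of their cells from 1 library, so cluster sizes were not compared between libraries.

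Counts of the kept cells were summed per library and given as CPM, the count of a gene scaled to the same total in each library. The heart library held 42241162 UMIs in kept cells and the spleen library 56239410, so that a count of 0, which allows up to 3 counts, limits a gene to 0.0710 CPM and 0.0533 CPM. Ratios are log2 of (CPM + 1) in heart over (CPM + 1) in spleen, which understates the difference for low genes. Intervals are exact 95% Poisson intervals for CPM and exact (Clopper-Pearson) binomial intervals for shares. All of them cover counting error only. With 1 library per group there was no test and no p-value, and tissue and library cannot be told apart. Cells were not treated as replicates.

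Genes with at least 50 CPM in either library were counted as higher or lower at a difference of at least 2-fold, as a description of size. The genes named were the 12 with the highest and the 12 with the lowest ratio, leaving out receptor and immunoglobulin segments, mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed genes. Ldha, Ldhb, Tcf7, Ifng, Foxp3 and Mki67 were always named, with up to 4 members of each gene list. Other members are named where a list is counted out. Some genes that the rule takes are not reported here. For each of 26 lists, the median ratio of members with at least 10 CPM in either library was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list needed at least 3 such members, which 21 lists had. Markers of 13 other cell types were read in the kept cells. Shares of cells were computed after thinning each cell to 1000 UMIs. A cell counted as cycling with at least 2 thinned UMIs of 10 cycling markers. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 denotes.

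The functions were tested on simulated data for heart against spleen, over 2320 genes. All 4-fold changes were recovered (100%), with 0 unchanged genes called. The ratio intervals covered 95.8% of the true ratios, and 3.5% of unchanged lists lay outside the central 95% of random lists. Both simulated libraries were drawn from the spleen profile with counting error alone, and changed genes had at least 100 CPM. Variation between libraries was not simulated, so these values check the functions and not the error of the calls in the real libraries. Alternatives chosen before the data were examined were other cell filters, cell calling and doublet treatments, other cell types kept, thinning, means of per-cell CPM, TMM factors (edgeR 4.0.16), centring, totals without mitochondrial, ribosomal protein and Malat1 counts, other pseudocounts and CPM floors, cells with few cycling UMIs, other random lists and other cluster resolutions. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.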

Results

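TEa CD4 T cells from heart allografts and spleens were profiled to ask how alloantigen-specific T cells differ between the graft and the lymphoid organ, and what the loss of Ldha changes. Ldha encodes the A subunit of lactate dehydrogenase, which converts pyruvate to lactate at the end of glycolysis. After filtering, 3985 wild-type cells from the heart allograft and 6569 from the spleen were kept, with medians of 8235 and 7988 UMIs and 2150 and 2184 genes per cell. The Ldha-deficient spleen library held 12466 cells with a median of 8114 UMIs. There was 1 library in each group, so no difference has a replicate check.

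The kept cells had T cell markers and the segments of the TEa receptor, the latter at lower shares in spleen. T cell markers summed to 11565 CPM in the heart library and 11327 CPM in the spleen library. Trbv19, the segment that encodes the V beta 6 chain of the TEa receptor, made up 87.7% of Trbv UMIs in heart cells (95% interval 85.9 to 89.2%) and 78.9% in spleen cells (76.9 to 80.7%). Its level was 33.0 CPM in heart and 25.2 CPM in spleen. The Trav14 family, which encodes V alpha 2, made up 78.8% (77.4 to 80.1%) and 58.7% (57.3 to 60.0%) of Trav UMIs, and its member Trav14d-3-dv8 was at 66.6 and 49.8 CPM. Whether cells with other receptors were more common in the spleen library was not tested. Xist was at 857 CPM in heart and 901 CPM in spleen, Tsix at 10.2 and 13.2 CPM, and Y-linked transcripts summed to 1.75 CPM (1.38 to 2.20) and 1.96 CPM (1.61 to 2.36).

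Markers of other cell types were also summed in the kept cells. The sums, heart first and spleen second, were 17.1 and 5.35 CPM for CD8 T cells, 44.4 and 181 CPM for B cells (of which Ighm made up 42.7 and 176 CPM), 0.71 and 0.78 CPM for plasma cells, and 15.5 and 6.52 CPM for dendritic cells. Neutrophil markers summed to 0.06 and 0.04 CPM, NK cell markers to 3.53 and 11.3 CPM, and platelet markers to 0.23 and 0.19 CPM. Cardiomyocyte markers were at 0.17 and 0.14 CPM, and fibroblast markers at 0.21 and 0.11 CPM. Endothelial markers were at 29.1 and 63.5 CPM, nearly all of it Pecam1 (28.0 and 63.0 CPM). Erythroid markers differed most, at 0.070 CPM in heart and 204 CPM in spleen. Monocyte or macrophage markers summed to 331 and 204 CPM, most of it Ctss (206 and 130 CPM) and Cst3 (119 and 71.8 CPM), while Lyz2 was at 1.04 and 0.27 CPM. Gamma delta T cell segments summed to 400 and 553 CPM, nearly all of it Trdc (397 and 551 CPM). These single markers were picked after their values had been seen.

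The targeted gene was examined first. Ldha (chromosome 7, 46841475 to 46855627, plus strand) was at 1051 CPM (1041 to 1061) in wild-type heart cells and 480 CPM (475 to 486) in wild-type spleen cells, a log2 ratio of 1.13. The ratio of the libraries had a counting interval of 2.16 to 2.22. In settings chosen after seeing the data, the log2 ratio of Ldha was 0.72 between the clusters with Th1-like markers (heart cluster 2 and spleen cluster 4). It was 0.64 with heart cluster 3 added and 1.13 in cycling cluster 5. Ldhb, the other main subunit (chromosome 6, 142490249 to 142507957, minus strand), was low in both, at 10.5 CPM (9.58 to 11.6) and 14.9 CPM (13.9 to 15.9). Ldha in the Ldha-deficient library was not analysed here, so the genotype label was not checked.

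Wild-type cells of the graft and of the spleen differed widely in expression. Graft cells had higher transcripts of effector, cytotoxic, inhibitory receptor and exhaustion, tissue residency and glycolysis genes, and lower transcripts of naive and stem-like genes. Among 2706 genes with at least 50 CPM in either library, 318 were at least 2-fold higher and 131 at least 2-fold lower in heart cells. The higher genes were 70.8% of these. With totals that left out mitochondrial, ribosomal protein and Malat1 counts the balance turned, to 328 higher and 367 lower (47.2% higher) among the 3970 genes that then passed the floor. Over the same genes as before, an added setting chosen after seeing the data, they gave 265 higher and 203 lower (56.6% higher). Ribosomal protein genes took 29.8% of UMIs in heart cells and 35.2% in spleen cells. Tissue and library cannot be told apart in these values.

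**Figure D1:**
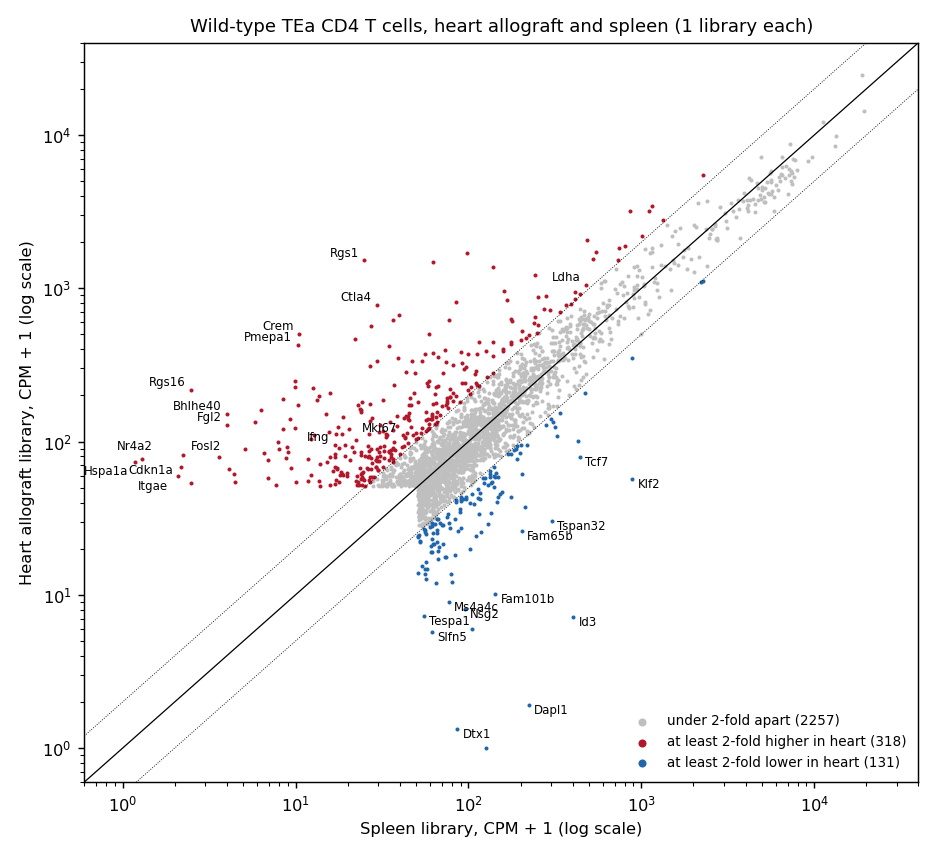
Levels of each gene with at least 50 CPM in either wild-type library, as CPM + 1 on log axes, with spleen on the horizontal and heart allograft on the vertical axis. Dotted lines mark 2-fold differences, and 318 genes lie on or above the upper line and 131 on or below the lower line.

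The 12 genes with the highest ratios included regulators of signalling from receptors. Rgs16 (chromosome 1, 153740349 to 153745468), a regulator of G protein signalling, was at 216 CPM in heart and 1.48 CPM in spleen (log2 ratio 6.45). Rgs1 (chromosome 1, 144242296 to 144249242), of the same family, was at 1523 and 24 CPM (5.93). Ctla4 (chromosome 1, 60887000 to 60915832), an inhibitory receptor, was at 782 and 28.6 CPM (4.72). Transcription factors in this group were Nr4a2 (75.4 and 0.30 CPM), Crem (505 and 9.50 CPM), Bhlhe40 (151 and 3.01 CPM) and Fosl2 (80.2 and 1.24 CPM). The others were the heat shock gene Hspa1a (72.1 and 0.18 CPM), Pmepa1, an antagonist of TGF-beta signalling (428 and 9.28 CPM), Fgl2 (128 and 3.01 CPM), the cell cycle inhibitor Cdkn1a (67.7 and 1.17 CPM) and Itgae, the integrin CD103 (58.6 and 1.08 CPM).

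The 12 genes with the lowest ratios included regulators of naive and recirculating T cells. Dapl1 (chromosome 2, 59484653 to 59505020) was at 0.92 CPM in heart and 222 CPM in spleen (log2 ratio -6.86), and Dtx1 at 0.33 and 85.0 CPM (-6.01). Id3 (chromosome 4, 136143497 to 136145755), an inhibitor of E proteins, was at 6.20 and 401 CPM (-5.80). Klf2 (chromosome 8, 72319033 to 72321656), a transcription factor of T cell egress, was at 56.2 and 883 CPM (-3.95). Others of these genes were Fam101b (9.19 and 142 CPM), Nsg2 (7.13 and 93.9 CPM), Slfn5 (4.73 and 60.3 CPM), Tspan32 (29.3 and 303 CPM), Ms4a4c (7.95 and 75.9 CPM), Fam65b (25.1 and 202 CPM) and Tespa1 (6.32 and 54.1 CPM).

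Genes of naive, stem-like and central memory T cells were lower in the graft. The median log2 ratio of 14 members was -1.37, at percentile 0 of random lists, with 9 members at least 2-fold lower. Among these were Id3, Klf2, Tcf7, Lef1, S1pr1, Slamf6, Bach2 and Bcl2. In settings chosen after seeing the data the list median was -1.46 between the Th1-like clusters (heart cluster 2 and spleen cluster 4) and -0.70 in cycling cluster 5. Tcf7, a transcription factor of stem-like T cells (chromosome 11, 52252371 to 52283014), was at 77.9 CPM (75.2 to 80.6) in heart and 439 CPM (434 to 445) in spleen.

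Effector genes were higher in the graft. The Th1 list had a median of 1.78 over 17 members (percentile 100), and 10 members were at least 2-fold higher. Between the clusters with Th1-like markers alone (heart cluster 2 and spleen cluster 4), a setting chosen after seeing the data, the median was reversed at -0.58 (percentile 0.1), and some Th1 genes define these clusters. Cluster 2 was named from higher Cxcr6, Nkg7 and Gzmb, and cluster 4 from higher Ccl5, Nkg7, Id2 and Il18rap. Only Nkg7 is in both sets, so these are not matched cells. The pair leaves out heart cluster 3 (1207 heart cells, with higher Ifng and Ccl5). The heat shock genes Hspa1b and Hspa1a marked cluster 3 most, with Ifng, Nr4a2 and Junb also among its top 10 genes. With cluster 3 added, also after seeing the data, the Th1 median was -0.45 (percentile 1.86). Ifng (chromosome 10, 118441046 to 118445892), the main Th1 cytokine, was at 94.2 CPM (91.3 to 97.1) in heart and 16 CPM (14.9 to 17.0) in spleen. The chemokine receptor Cxcr6 was at 334 and 28.6 CPM, Il12rb2 at 28.9 and 1.72 CPM, and Zeb2 at 16.2 and 1.14 CPM. The cytotoxic list had a median of 2.44 over 9 members (percentile 100), with 8 at least 2-fold higher, and was smaller between the Th1-like clusters (1.11) and in cycling cluster 5 (0.96), both chosen after seeing the data. Gzmb was at 336 and 53.0 CPM, Gzmk at 119 and 7.45 CPM, Ctsw at 419 and 33.7 CPM, and Klrc1 at 12.1 and 0.96 CPM.

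Inhibitory receptor and exhaustion genes had a median of 2.63 over 11 members (percentile 100), of which 8 were at least 2-fold higher and 2, Tox and Cd160, at least 2-fold lower. The lowest median under the settings chosen before the data were examined was 0.999. In settings chosen after seeing the data it was 2.02 between the Th1-like clusters and 1.07 in cycling cluster 5. The cytokine Il10 was at 26.8 CPM (25.3 to 28.4) in heart and 0.27 CPM (0.15 to 0.44) in spleen, and Havcr2 at 10.9 and 0.46 CPM. The residency and homing list had a median of 2.08 over 14 members (percentile 100), with 12 at least 2-fold higher, among them Rgs2 (133 and 4.85 CPM). In settings chosen after seeing the data it was 0.82 between the Th1-like clusters and 0.78 in cycling cluster 5. Itga4 was at least 2-fold lower.

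Lists of other T helper types gave mixed values. The Treg list had a median of 2.55 over 8 members (percentile 100), led by genes that activated T cells also express: Ctla4 (782 and 28.6 CPM), Tnfrsf4 (569 and 26.2 CPM), Il2ra (29.2 and 1.12 CPM) and Capg (334 and 46.3 CPM). Foxp3, the lineage factor of regulatory T cells, was at 2.84 CPM (2.36 to 3.40) in heart and 0.44 CPM (0.29 to 0.66) in spleen. The Tfh list had a median of -0.63 over 10 members (percentile 0.14), which turned to 0.41 with members of at least 50 CPM and, in a setting chosen after seeing the data, to 0.12 between the Th1-like clusters. Cxcr5 (3.65 and 35.6 CPM) and Btla (6.84 and 47.9 CPM) were lower in heart, and Icos (957 and 160 CPM) and Pdcd1 (234 and 36.2 CPM) higher. For Th2 and Th17, 1 member each was measured: Gata3 (44.3 and 48.2 CPM) and Rora (112 and 17.6 CPM).

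**Figure D2:**
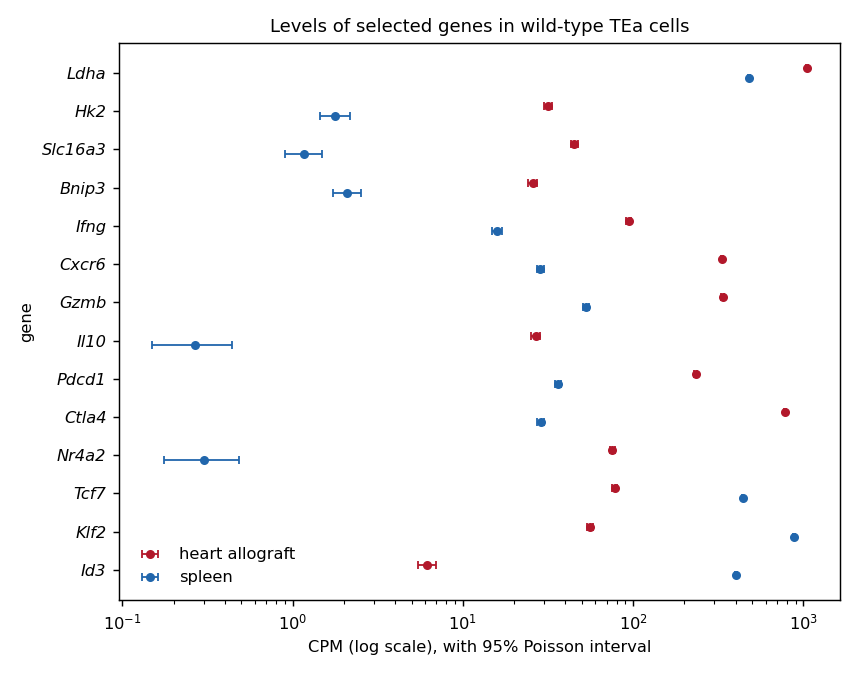
CPM of selected genes in the heart allograft and spleen libraries on a log axis, with exact 95% Poisson intervals, which cover counting error only and are narrower than the points for many genes. Tcf7, Klf2 and Id3 lie lower in heart, and the other genes shown, Ldha among them (1051 and 480 CPM), lie higher.

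Glycolysis genes were higher in the graft as a group. The list without Ldha had a median of 1.35 over 17 members (percentile 100), with 12 at least 2-fold higher and 1, Pdk1, at least 2-fold lower. The lactate exporter Slc16a3 was at 45.2 CPM (43.2 to 47.3) in heart and 1.17 CPM (0.91 to 1.49) in spleen. Hexokinase Hk2 was at 31.5 and 1.78 CPM, Tpi1 at 351 and 38.1 CPM, and Aldoa at 1221 and 240 CPM. The list of HIF targets outside glycolysis, which also holds the HIF gene Hif1a itself, had a median of 1.14 over 10 members (percentile 99.98). The lowest median of this HIF list under the settings chosen before the data were examined was 0.73. In settings chosen after seeing the data it was 0.94 between the Th1-like clusters and 0.76 in cycling cluster 5. Hif1a was at 384 and 89.7 CPM, Bnip3 at 25.8 and 2.10 CPM, and Ndrg1 at 13.5 and 0.75 CPM, while Ddit4 was lower in heart (32.6 and 114 CPM), though not in cycling cluster 5 (log2 ratio 0.29), a setting chosen after seeing the data.

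Other metabolic lists lay closer to random lists. Oxidative phosphorylation had a median of 0.26 (percentile 82.3), with Cox5a (640 and 368 CPM), Sdhb (162 and 108 CPM), Atp5b (544 and 365 CPM) and Cox7a2 (441 and 317 CPM) farthest from equal. The tricarboxylic acid cycle had a median of 0.01 (percentile 63.9), with Suclg1 at 79.2 and 154 CPM, Idh3b at 97.4 and 68.0 CPM, Idh2 at 24.1 and 33.8 CPM and Dlst at 14.4 and 20.3 CPM. Fatty acid oxidation had a median of 0.02 (percentile 68.9), with Acadl at 122 and 52.9 CPM, Slc25a20 at 24.1 and 14.9 CPM, Cpt1a at 18.4 and 13.9 CPM and Etfb at 108 and 93.8 CPM. Sterol and fatty acid synthesis had a median of -0.41 (percentile 15.3), with Fdps at 28.3 and 57.4 CPM, Sqle at 5.54 and 10.5 CPM, Idi1 at 10.3 and 18.6 CPM, and Insig1 at 27.0 and 13.6 CPM. Amino acid transport and one-carbon synthesis had a median of 0.45 (percentile 99.1), which lay within the central 95% of random lists when cells were thinned (0.17), without cells over 3 times the median UMI count (0.34) and with mean per-cell CPM (0.31). Got1 was at 162 and 22.6 CPM, Slc3a2 at 378 and 61.1 CPM, Slc38a2 at 120 and 19.4 CPM, and Phgdh at 117 and 68.6 CPM.

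**Figure D3:**
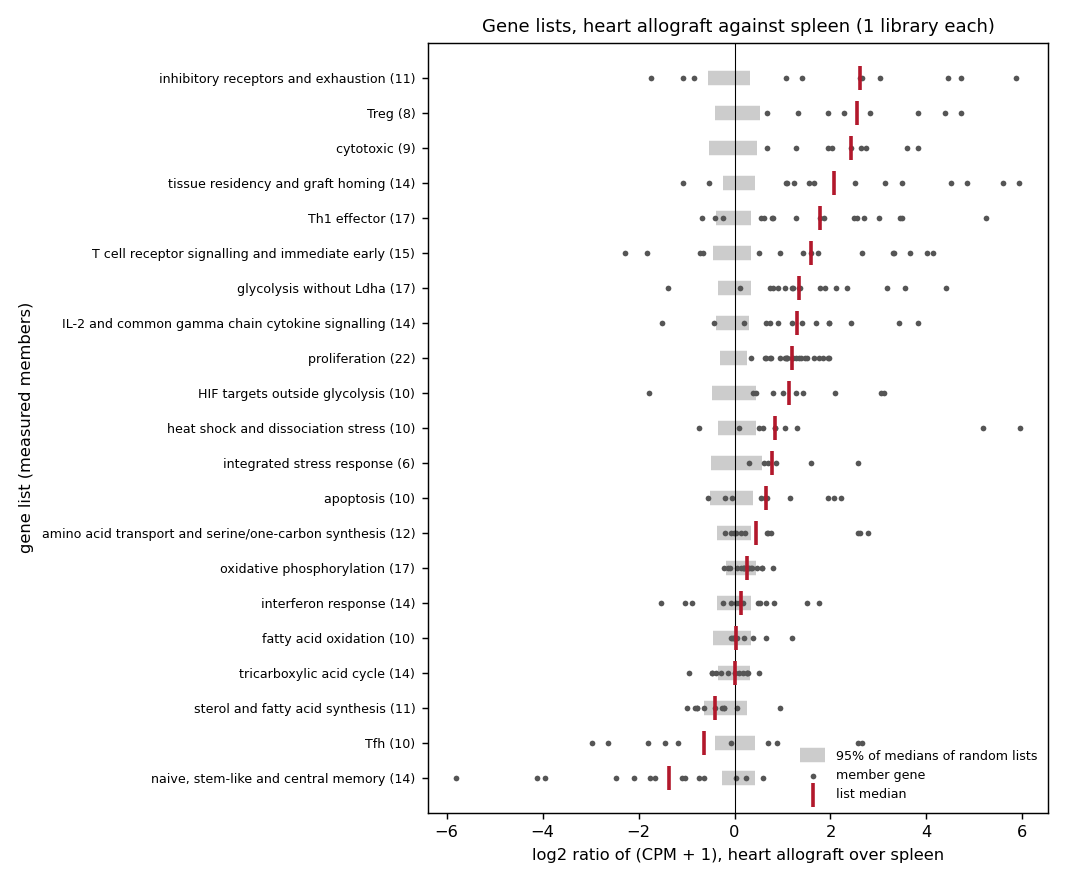
Log2 ratio of (CPM + 1), heart allograft over spleen, of each measured member of 21 gene lists (points), with each list's median (red line) and the central 95% of medians of 10000 matched random lists (grey bar). Medians range from -1.37 for naive and stem-like genes to 2.63 for inhibitory receptor and exhaustion genes.

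T cell receptor signalling and immediate early genes had a median of 1.59 over 15 members (percentile 100), with 9 at least 2-fold higher and 2, Egr2 and Myc, at least 2-fold lower. In all, 11 members were higher and 4 lower, the lower ones including Egr1 (33.6 and 55.7 CPM) and Cd40lg (29.9 and 47.9 CPM). The list joins both kinds of genes, so its median is no measure of receptor signalling alone. Tnfaip3 was at 222 and 11.6 CPM, Dusp1 at 65.7 and 3.13 CPM, Nr4a3 at 82.6 and 5.60 CPM, and Fosb at 20.1 and 1.10 CPM. Heat shock genes had a median of 0.84 over 10 members (percentile 99.87), with Hspa1b at 41.9 and 0.18 CPM, Dnajb1 at 106 and 41.9 CPM, and Hspa8 at 2787 and 1338 CPM. Of the kept cells, 466 heart cells and 18 spleen cells held an Hspa1a or Hspa1b UMI. Without these cells, a setting chosen after seeing the data, the heat shock median was 0.45 (percentile 95.6), within the central 95% of random lists. The selection itself takes out Hspa1a and Hspa1b, which is part of this fall. The integrated stress response had a median of 0.78 (percentile 99.1), with Ppp1r15a at 49.1 and 7.38 CPM, Atf4 at 136 and 44.3 CPM, Hspa5 at 435 and 238 CPM and Herpud1 at 74.0 and 45.1 CPM.

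IL-2 and common gamma chain signalling genes were higher in heart as a group, with a median of 1.31 over 14 members (percentile 100). Of these, 8 were at least 2-fold higher and 1, the cytokine gene Il2 itself, at least 2-fold lower (6.18 and 19.6 CPM). Cish was at 74.3 and 5.97 CPM, Pim1 at 358 and 65.5 CPM, and Socs2 at 31.8 and 7.43 CPM, which was reversed between the Th1-like clusters (log2 ratio -0.37), a setting chosen after seeing the data. Apoptosis genes, a list of survival and death genes, had a median of 0.66 over 10 members (percentile 99.7), which lay within the central 95% of random lists with members of at least 50 CPM (0.56). Of the 10 members, 3 were lower in heart, with both survival and death genes among the 4 that were at least 2-fold higher, such as Bcl2l1 (46.0 and 9.07 CPM), Pmaip1 (14.7 and 2.70 CPM) and Bcl2l11 (134 and 34.0 CPM). Interferon response genes had a median of 0.13 (percentile 83.1), or 0.60 (percentile 97.95) with members of at least 50 CPM, with Isg20 (153 and 44.4 CPM) and Gbp2 (66.5 and 22.7 CPM) higher and Usp18 (5.52 and 17.9 CPM) and Ifit1 (20.4 and 42.5 CPM) lower.

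Proliferation genes were higher in the graft, with a median of 1.20 over 22 members (percentile 100), all 22 of them higher and 16 at least 2-fold. Mki67 was at 109 CPM (105 to 112) in heart and 40.8 CPM (39.2 to 42.5) in spleen. Stmn1 was at 448 and 114 CPM, Ccnb2 at 62.8 and 15.4 CPM, Rrm2 at 84.5 and 22.8 CPM, and Birc5 at 142 and 41.2 CPM. In settings chosen after seeing the data, the list median was reversed between the Th1-like clusters (-0.18) and within cycling cluster 5 (-0.14), inside the central 95% of random lists in both. Values also reversed for Mki67 in both (-0.65 and -0.16), and for Stmn1 (-0.72), Ccnb2 (-2.29) and Birc5 (-2.23) between the Th1-like clusters. The clustering had already sorted cells by such genes, so these reversals are no measure of the difference between the whole libraries. A second cluster with cycling markers, cluster 9 (5 heart and 72 spleen cells), is not part of cluster 5. After thinning to 1000 UMIs, 9.13% of heart cells (8.26 to 10.1%) and 2.07% of spleen cells (1.74 to 2.44%) were cycling, and no kept cell was too shallow for this. The same rule gave 32.0% and 8.24% without thinning. In spleen cells of cluster 0, with naive or stem-like markers, the share after thinning was 0.139% (0.0378 to 0.355%), but the clustering had already set cycling cells apart from it, so this is no independent background, and none is given for heart. In free RNA the cycling markers summed to 637 CPM in heart and 233 CPM in spleen, against 785 and 276 CPM in kept cells. Free RNA of heart held erythroid markers at 205 CPM and dendritic cell markers at 693 CPM, against 0.070 and 15.5 CPM in kept cells. Monocyte or macrophage markers lay closer (852 and 331 CPM), with Ctss and Cst3 most of the latter. The erythroid and dendritic cell values, picked after seeing the data, argue against free RNA as the source of most cycling UMIs in heart cells. In spleen, erythroid markers were at 357 and 204 CPM, so what free RNA adds to the share there stayed open.

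Ldha-deficient cells were compared with wild-type spleen cells only by depth and complexity. Their 12466 cells held 112175903 UMIs, with a median of 2566 rows per cell against 2184 genes in wild-type spleen cells. After thinning to 1000 UMIs the medians were 589 rows in Ldha-deficient, 511 in wild-type spleen and 533 in wild-type heart cells. The 50 highest rows took 28.8%, 35.9% and 31.0% of UMIs. The matrices differ in their number of rows and in the Cell Ranger version of their headers. Fewer filters were also applied to the Ldha-deficient barcodes, so these values carry no direction for the genotype.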

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

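All tests in this part were chosen after the barcodes they describe had been seen. A signal outside the compared cells came from the cluster with monocyte or macrophage markers, which held 2.14% of heart barcodes (87, 95% interval 1.72 to 2.63%) and 0.213% of spleen barcodes (14, 0.116 to 0.357%). Y-linked transcripts were at 73.0 CPM in those heart barcodes and at 1.75 CPM in the kept heart T cells. They were at 115 CPM (64.5 to 190, from 15 UMIs) in those spleen barcodes and at 1.96 CPM in the kept spleen T cells, so they were not particular to the graft. In the spleen, 10 of the 14 had at most 5 T cell marker UMIs and carried Igkc at 150641 CPM, and the other 4 carried Hbb-bs at 68335 CPM.

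In the heart library, 62 of the 87 barcodes (71.3%, 60.6 to 80.5%) held over 5 T cell marker UMIs together with the myeloid markers, with Lyz2 at 3873 CPM and Cd74 at 5564 CPM. Their median depth was 28454 UMIs, against 8235 in kept T cells, and they held both Xist (450 CPM) and Y-linked transcripts (68.2 CPM), whereas the 25 barcodes with few T cell UMIs held 0 Xist UMIs and 115 CPM of Y-linked transcripts. Shared barcodes of a T cell with Xist and a myeloid cell with Y-linked transcripts may therefore be their source. Random sharing of droplets at loading was argued against, since at most 9.71% of droplets held a cell. Attachment of the cells before sorting, whether in the graft or during tissue processing, stayed open, and no biological explanation was tested.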

How the results depend on the processing

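Of 21 list medians, 17 stayed on the same side of the central 95% of random lists under all settings that had been chosen before the data were examined and could be run. The other 4 were the amino acid, Tfh, interferon response and apoptosis lists. Not every setting could move these results. Keeping the marked doublets added back only 2 barcodes, and the other cluster resolutions gave the same values. TMM factors and centring shift a list and its random lists nearly alike. The count of higher genes was within 1.5 times of 318 in 18 of 20 settings (280 to 376), and that of lower genes within 1.5 times of 131 in 17 (103 to 149). With a floor of 20 CPM there were 493 higher and 344 lower genes, and with 100 CPM 199 and 64, as more or fewer genes were tested. Totals without mitochondrial, ribosomal protein and Malat1 counts gave 328 higher and 367 lower genes (47.2% higher), partly because 3970 genes then passed the floor. Over the same genes as before, a setting chosen after seeing the data, 203 were lower. The median ratio of genes over 50 CPM in both libraries was 0.04, 0.14 with TMM factors, where 78.5% of calls were higher, and -0.13 with those totals.

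The log2 ratio of Ldha was positive in all 17 such settings, and 8 moved it past its counting interval: 1.10 with at most 5% mitochondrial UMIs, 0.98 without cells over 3 times the median UMI count, 0.97 with thinning, 0.96 with mean per-cell CPM, 1.24 with TMM factors, 1.08 with centring, 0.96 with totals without ribosomal protein and the other genes, and 1.03 in cells with at most 1 cycling UMI. The cause was not tested. Cycling shares in heart and spleen were 18.9% and 6.00% at 1 UMI, 5.65% and 1.52% at 3 UMIs, 32.0% and 8.24% without thinning, and 13.6% and 2.94% at 2000 UMIs, as the rule and depth dictate. The Tfh median turned to 0.41 with members of at least 50 CPM, which leaves fewer members. Of 1819 such values of named genes, 848 stayed within their counting interval, 971 moved and 0 reversed. Only genes at least 2-fold apart could count as reversed, so a change of sign in a smaller ratio is not counted there.

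Other settings were chosen after seeing the data. Between the Th1-like clusters (heart cluster 2, spleen cluster 4), and then with heart cluster 3 added, Ldha was at 0.72 and 0.64, and values reversed for Mki67 (-0.65 and -0.63), Stmn1 (-0.72 and -0.43), Ccnb2 (-2.29 and -1.95), Birc5 (-2.23 and -1.79), Socs2 (-0.37 and -0.58) and the Th1 (-0.58 and -0.45), Tfh (0.12 and 0.0673) and proliferation (-0.18 and -0.17) lists. Some Th1 genes also define these clusters, and the clustering had already set clusters with cycling markers apart from them. Within cycling cluster 5 there were 194 higher genes, and values reversed for Mki67 (-0.16), Ddit4 (0.29) and the proliferation list (-0.14). The cause was not tested. The alternatives planned for Ldha-deficient against wild-type cells, and for Ldha in that library, were not run, because its rows were not named here. No paired analysis was possible because each group has 1 library and no test was made. Depth limits genes below about 0.0710 CPM in heart and 0.0533 CPM in spleen.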

Other observations

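All tests in this part were chosen after the results they bear on had been seen, except the totals without ribosomal protein counts, which had been chosen before the data were examined. Between the clusters with Th1-like markers (heart cluster 2, 2149 cells, and spleen cluster 4, 890 cells), some list medians stayed outside the range of random lists and others did not. The inhibitory receptor and exhaustion list had a median log2 ratio of 2.02, the T cell receptor and immediate early list 2.88, the HIF list 0.94 and the naive and stem-like list -1.46. With heart cluster 3 added these lists were at 1.77, 3.51, 0.85 and -0.91. Within cycling cluster 5 (610 heart and 104 spleen cells) the same lists were at 1.07, 2.18, 0.76 and -0.70. The residency list (2.08 over all kept cells) was at 0.82 between the Th1-like clusters and 0.78 in cycling cluster 5, and the cytotoxic list (2.44) at 1.11 and 0.96. The Th1 list was at -0.58 and 0.24. Between the Th1-like clusters the amino acid list (0.30, percentile 97.2) and the apoptosis list (0.30, percentile 97.3) lay within the central 95% of random lists. With heart cluster 3 added, both lay outside it (0.28, percentile 97.84, and 0.46, percentile 99.45). In cycling cluster 5 the amino acid list lay within it (0.036, percentile 85.3) and the apoptosis list outside (0.47, percentile 99.5). These clusters hold cells chosen by expression, and each library is 1 sample.

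The glycolysis list was higher in the heart library, and more cycling cells there may be one source. Within cycling cluster 5, where the proliferation list was not higher in heart (-0.14), its median was still 1.27, which argues against cycling as the whole cause. This comparison left out cycling cluster 9 (5 heart and 72 spleen cells), so it covers only part of the cycling cells. Between the Th1-like clusters the glycolysis median was 1.12, also at percentile 100 of random lists, so cells with Th1-like markers differed too. Each of these clusters came wholly or nearly so from 1 library, and the Th1 list differed between them (-0.58). They are thus not matched cells, and whether a larger share of Th1-like cells is the cause was not decided. With totals that left out ribosomal protein, mitochondrial and Malat1 counts the glycolysis median was 1.14. That value bears on its size only, since a change of totals moves all genes of a library alike. The tissue itself and any difference in handling between these libraries stayed open, as untested.

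The T cell receptor and immediate early list was also higher in the heart library, where 466 cells held an Hspa1a or Hspa1b UMI, against 18 in the spleen. Those cells are a candidate cause. In cells without such a UMI the median was 1.39 (percentile 100), which argues against them as the whole cause. The heat shock list was at 0.45 there (percentile 95.6), against 0.84 over all kept cells, partly because the selection takes out Hspa1a and Hspa1b, and Dnajb1 was at 1.16. A heat shock response in cells without such a UMI stayed open. Immediate early induction in all cells of the library during tissue processing cannot be told apart from a difference between tissues, since there was 1 library per tissue.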
